A study of Mus musculus with 4 samples.

How the data were processed

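Total RNA from intact whisker dermal papillae and from cultured papilla cells of mice was measured on 4 Agilent arrays with 1 colour, 1 array for each of the intact papilla, P0, P5 and tP18. Per the labels, papillae came from 4-week-old animals, and cells were grown for 10 to 14 days in low glucose medium with 10% fetal bovine serum and 10 ng/ml FGF2. Per the labels, cDNA was amplified with the Ovation Pico WTA System V2 and labelled with Cy3 using the SureTag kit, and the amount of RNA that entered the amplification is not given in the sources used here. A further label of the intact sample gives its culture stage as that of untransfected cells, and its title, description and source were followed instead.

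The deposited spot intensity (gProcessedSignal) is a linear, background-subtracted and detrended signal made with Agilent Feature Extraction, whose version is 11.5.1.1 per the file headers and 12.0.3.1 per the submitters' processing notes. Per the file headers the array design was annotated to the mm9 build, all 4 arrays lay on 1 slide and were scanned in 1 scan, so neither differs between groups. The authors' value table of the series held the same intensities times a constant of 7.70 for the intact array, 7.92 for P0, 7.69 for P5 and 6.95 for tP18, with column medians of 351, 309, 162 and 191. Its scale is therefore linear, it is not centred, and it served as an alternative.

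Each array held 62976 spots, of which 3671 were control spots and were left out. Between 140 and 158 spots per array had the software's outlier flags, and the flagged spots rather than the whole replicated probes were left out. Spots of a probe were averaged, and a probe counted as well above background where at least 50% of its spots were so flagged. The value of a probe was log2 of the intensity minus the array's 75th percentile over non-control probes, which was 218 in the intact papilla, 209 in P0, 154 in P5 and 183 in tP18. The median coefficient of variation of replicated spots given in the file headers was 6.94%, 6.77%, 6.05% and 6.33%, and the median SD over 399 probes printed in 10 spots was 0.11, 0.10, 0.09 and 0.10 on the log2 scale. The error of a gene's difference combines the software's error of both spots and covers no biological spread, and the number of arrays limits the precision.

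The files used held no gene symbols, so probes were named by matching RefSeq accessions without version to a table of mouse genes (assembly GRCm38), from which no coordinates were taken. Of 55681 probes, 28026 matched 1 symbol and 27655 matched none, giving 21151 genes, of which 5681 had several probes. The probe with the highest mean over the 4 arrays stood for its gene. Among genes with several measured probes, the median SD of a difference between probes lay between 0.18 and 0.29, and between 3 and 62 genes per comparison had probes at least 2-fold apart in opposite directions.

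All 6 pairs of groups were compared, and a gene counted as higher or lower where it differed at least 4-fold. A gene not well above background on 1 array was set to the higher of its own signal and the lowest signal among probes well above background there, and its difference is given as at least N-fold. Where its own signal was the higher, the bound equals the measured difference, and spot error may put the true fold below it. This held for Rspo3 in P0 and for Enpp2 in P5 and tP18, each against the intact papilla, among others. There were 26 gene lists fixed before the data were examined, 18 of pathways and 8 of markers of other cell types. Each list is described by the median log2 difference of members well above background on at least 1 of both arrays, as measured, and by the percentile of that median among 10000 random lists of the same size matched in 20 bins of mean expression. For lists with members not well above background, the median with those members at their bounds is given beside the median as measured where a list is described at length. Listed genes named in older symbols appear under current ones, such as Ccn4 and Ccn5.

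The named genes were chosen by a rule fixed beforehand: 10 key genes (Tert, Bmi1, Cdkn2a, Cdkn1a, Alpl, Vcan, Sox2, Lef1, Corin and Bmp4), up to 3 members per direction of each list described, the 5 highest and 5 lowest genes of each comparison, and, in comparisons with the intact papilla and of tP18 with P5, the 3 largest bounds per direction; some of the genes so chosen are not reported here. The procedure was run on simulated data in which the intact array's levels stood for both arrays. Only spot error was added, changed genes were drawn from bright genes, and no P5 value entered the differences. All genes with simulated log2 differences of 3 or 4 in size were called among 15973 genes, and 0 of 15754 unchanged genes were. With noise this small the outcome checks the calculation only. It does not show how often single arrays give false calls. A simulated list shifted by 1.5 gave a median of 1.54 at percentile 100, and 5 of 100 unshifted lists lay outside percentiles 2.5 to 97.5.

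Alternatives were another percentile base, the array median, quantile normalization, normexp correction with an offset of 50, the authors' value table, genes measured on both arrays only, the mean of a gene's probes, other fold thresholds, and unmatched random lists. The normexp alternative used median spot and background signals, because the files used did not hold the mean signal planned for it. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.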

Results

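Gene expression was measured in the dermal papilla of mouse whisker follicles and in cells grown from it. The dermal papilla is the cluster of mesenchymal cells at the base of a hair follicle that directs the growth of the hair, and its cells are known to lose this activity in culture. There were 4 groups with 1 array each: intact papillae dissected from whisker follicles of 4-week-old mice, cultured papilla cells at passage 0 (P0), cultured papilla cells at passage 5 (P5), and cells transfected with TERT and BMI1 at passage 18 (tP18). The study set out to compare transcripts related to the hair follicle between the intact papilla and these stages of culture. Because no group had replicates, differences were described by size, no test was run, and every error given as ± on the log2 scale is the scanner software's error of the spots alone. Of 55681 probes, 69.9% were well above background on the intact array, 67.5% on P0, 57.1% on P5 and 61.1% on tP18, and no spot was saturated.

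Tert and Bmi1, the mouse genes corresponding to those introduced, were read first. Intensities given here and below are not scaled between arrays, whereas folds and log2 differences are. Tert, the catalytic subunit of telomerase, was dim but well above background on every array, with an intensity of 63.6 in the intact papilla, 35.2 in P0, 20.7 in P5 and 29.3 in tP18. That flag does not by itself show that Tert was expressed. Of 1072 olfactory receptor genes, 26.8%, 22.7%, 13.2% and 18.8% were also well above background on these arrays. Tert in tP18 differed from P5 by a log2 value of 0.25 ± 0.28, and the sign of this difference depended on the scaling. Bmi1, a Polycomb repressor of the Cdkn2a locus, had an intensity of 351 in the intact papilla, 426 in P0, 420 in P5 and 748 in tP18. After scaling, it was 1.49-fold higher in tP18 than in P5 (log2 0.58 ± 0.20). A second Bmi1 probe differed less, at -0.90 in P5 and -0.65 in tP18 on the scaled log2 axis. Whether these probes match the sequences that were introduced is not given in the sources used here, so they check nothing about the transfection. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, had an intensity of 14.6 in the intact papilla, 421 in P0, 1427 in P5 and 522 in tP18. Cdkn1a, which encodes the inhibitor p21, had an intensity of 166 in the intact papilla, 1298 in P0, 1743 in P5 and 871 in tP18.

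**Figure D1:**
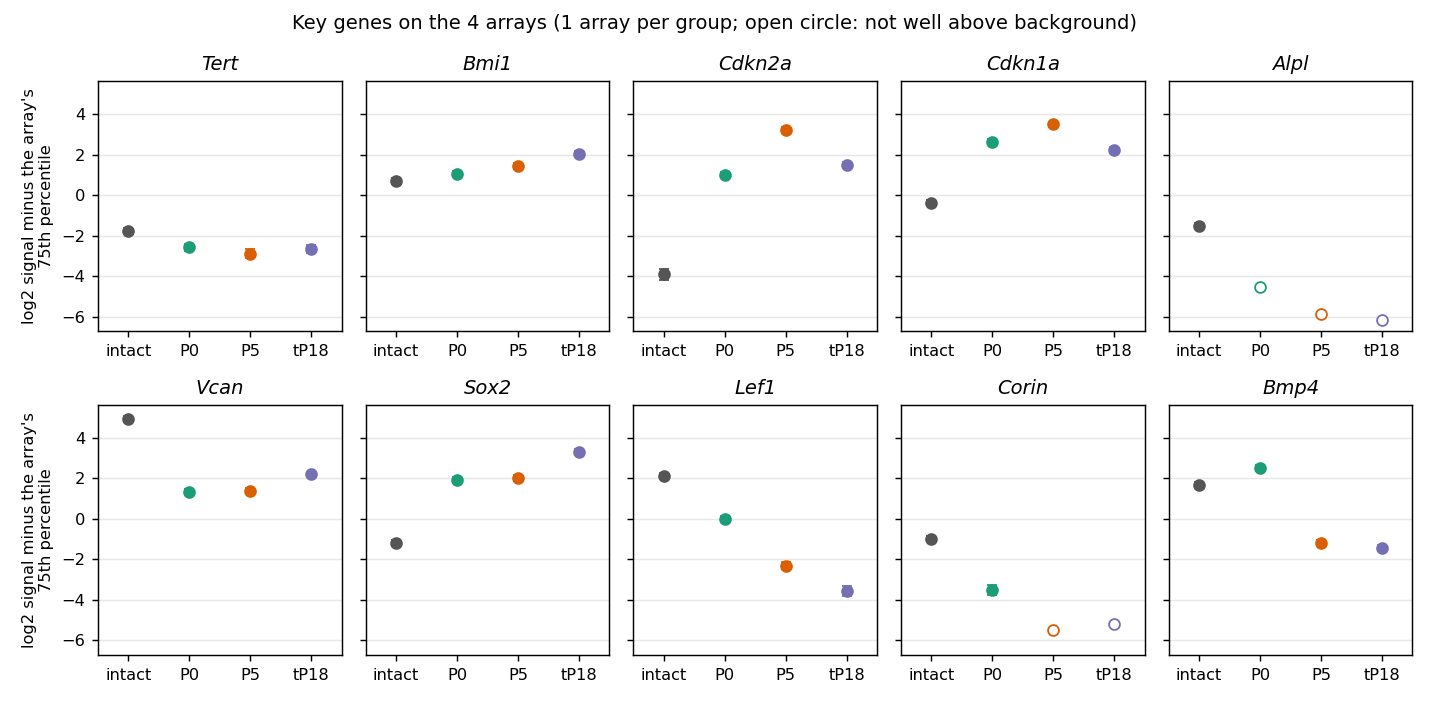
Level of 10 genes on the 4 arrays, as log2 signal minus the array's 75th percentile, with 1 point per array, the scanner's spot error as bars, and open circles for genes not well above background. Cdkn2a and Cdkn1a were lowest in the intact papilla and highest in P5, whereas Lef1 was highest in the intact papilla and lowest in tP18.

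In the primary culture, 8 of 16 p53 targets and CDK inhibitors and 7 of 13 contractile genes were at least 4-fold higher than in the intact papilla, while 9 of 28 genes characteristic of the papilla were lower and 4 higher. Mmp3, a matrix metalloproteinase, was 866-fold higher in P0 than in the intact papilla (log2 9.76 ± 0.33), and Thbs1, a matricellular glycoprotein, was 225-fold higher (log2 7.82 ± 0.21). The BMP antagonist Grem1, not well above background in the intact papilla, was at least 1120-fold higher in P0. Conversely, Vcan, a proteoglycan of the papilla matrix, was 12.3-fold lower (log2 -3.63 ± 0.20), and Alpl, the alkaline phosphatase used to stain papillae, was at least 7.08-fold lower. Among 16467 genes compared, 888 were at least 4-fold higher in P0 and 755 at least 4-fold lower, and the median of all genes differed by -0.04 on the log2 scale.

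The dermal papilla signature, a list of 29 genes fixed before the data were examined, had 28 measured members in this comparison, of which 4 were at least 4-fold higher and 9 at least 4-fold lower in P0. Its median log2 difference of -0.65 lay at percentile 0.06 of 10000 random lists matched on expression, which, here and below, describes these arrays only. Restricted to members well above background on both arrays, the median was -0.34 at percentile 2.89. In a division of the list made after the values were seen, the 12 members also known from follicle epithelium, vessels or nerve had 5 lower and none higher (median -1.19), and the 16 others had 4 lower and 4 higher (median 0.12, percentile 81.0). The lower members included Rspo3 (at least 46.3-fold), Enpp2 (38.5-fold), Prom1 (14.2-fold), Corin (5.74-fold) and Lef1 (4.27-fold). Rspo3 is a secreted amplifier of Wnt signals and Lef1 a transcription factor of the Wnt pathway. The higher members were led by Crabp1, a retinoic acid binding protein, at 103-fold, with the integrin Itga8 at 22.2-fold, Tbx18 at 9.77-fold and Sox2 at 8.94-fold. Bmp4 was 1.82-fold higher in P0 (log2 0.87 ± 0.20). Markers of other cells of the follicle moved with this list: 21 of 24 keratinocyte and hair shaft genes were at least 4-fold lower (median log2 -6.33, or -5.79 with bounds), as were 7 of 10 melanocyte genes (-5.03, or -4.43 with bounds) and 8 of 12 endothelial genes (-2.16). Of 14 immune genes, 3 were lower and 1 higher (median -0.68, percentile 0.56).

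The Wnt and Hedgehog lists had several lower members in P0. The arrays do not tell which cells of the dissected tissue expressed these lists, or the BMP and cell cycle lists, in the intact papilla. Of 14 measured Wnt targets, 6 were at least 4-fold lower, including Lgr5 (at least 19.2-fold) and Axin2 (9.09-fold), and 3 were higher, namely Ccn5 (at least 45.1-fold), Ccn4 (6.13-fold) and Ccnd1 (6.10-fold). The Wnt target median was -1.14 at percentile 0.15, and -0.43 at percentile 9.98 over members measured on both arrays. Of 10 Hedgehog genes, 4 were at least 4-fold lower and 1 was higher. The Hedgehog effector Gli1 was at least 33.2-fold lower, and the receptor gene Ptch1 was 8.94-fold lower. The Hedgehog median was -0.68 at percentile 1.19, and -0.24 at percentile 22.2 over members measured on both arrays. In the BMP list, 1 of 18 members was at least 4-fold higher and 2 were lower, the latter being Sostdc1 (74.4-fold) and Msx2 (18.3-fold), and the median of 0.13 lay at percentile 75.9.

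Of 16 p53 targets and CDK inhibitors, 8 were at least 4-fold higher in P0 and none lower, with a median of 2.14. They were led by Cdkn2a at 30.1-fold, Ccng1 at 20.1-fold and Cdkn2b at 10.9-fold. In the cell cycle list, Bub1b was 4.66-fold lower and the other 25 members differed by less than 4-fold, while the median of -1.19 lay below all 10000 random lists. Of 15 senescence-associated secretory genes, 7 were higher and 1 was lower (median 2.38, or 1.38 with bounds), with Mmp10 at least 155-fold higher and Igfbp5 40.4-fold lower. Extracellular matrix genes went both ways, with 13 of 24 at least 4-fold higher, such as Tnc (39.0-fold), Lox (30.7-fold) and Bgn (17.1-fold), and 3 lower, namely Dcn (153-fold), Eln (10.2-fold) and Col3a1 (6.00-fold). Of 13 contractile genes, 7 were higher, including Ccn1 (38.4-fold), Cald1 (17.8-fold) and Cnn2 (10.5-fold), and none lower.

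Over all genes measured on both arrays, the highest in P0 after Mmp3 were S100g (372-fold), Cck (272-fold), Thbs1 and Adm (196-fold). The lowest were genes of keratinocytes, red blood cells and the hair shaft: Krt5 (1520-fold), Hba-a2 (1360-fold), Prr9 (523-fold), Hba-a1 (457-fold) and Krtap8-1 (433-fold). Among genes measured on 1 array only, Akr1c18 and Spp1 were at least 204-fold and 200-fold higher in P0. Likewise, the gap junction gene Gjb2, the haemoglobin gene Hbb-bt and the hair keratin Krt35 were at least 775-fold, 594-fold and 534-fold lower. Under 4-fold in other settings were Lef1 with scaling to the median (log2 -1.92) and Alpl, Bub1b, Ccn4, Corin, Lef1 and Ptch1 with normexp.

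At passage 5, 12 of 13 contractile genes and 9 of 16 p53 targets and CDK inhibitors were at least 4-fold higher than in the intact papilla, and 14 of 28 signature genes were lower. The smooth muscle actin gene Acta2 was 52.4-fold higher in P5 than in the intact papilla (log2 5.71 ± 0.20). Cdkn2a was 138-fold higher (log2 7.11 ± 0.31) and Cdkn1a 14.9-fold higher (log2 3.90 ± 0.21). Lef1 was 21.4-fold lower (log2 -4.42 ± 0.23) and Bmp4 7.21-fold lower (log2 -2.85 ± 0.21). Among 16249 genes compared, 1448 were at least 4-fold higher and 982 at least 4-fold lower, so that 59.6% of these genes were higher. That share was 38.4% when arrays were scaled on probes detected on all 4 arrays, 34.7% in the authors' value table, 70.7% with normexp correction and 83.4% with scaling to the median.

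In the dermal papilla signature, 14 of 28 measured members were at least 4-fold lower in P5 and 8 were higher. The median was -2.35 (percentile 0), -1.76 with unmeasured members at their bounds, and -0.47 over members measured on both arrays. Enpp2 was at least 249-fold lower, Rspo3 at least 34.6-fold, Prom1 at least 24.5-fold, Vcan 11.7-fold, Corin at least 7.26-fold and Alpl at least 5.05-fold lower. Crabp1 was 125-fold higher, Tbx18 9.60-fold and Sox2 9.47-fold higher. Beside these, 22 of 24 keratinocyte and hair shaft genes were at least 4-fold lower (median log2 -6.35), as were 8 of 10 melanocyte genes (-6.13), 8 of 12 endothelial genes (-3.12) and 5 of 14 immune genes (-1.44), while 1 immune gene was higher. With bounds these medians were -5.80, -4.44, -2.40 and -1.28, and the immune median was -0.53 at percentile 5.10 over members measured on both arrays. Of 14 Wnt targets 8 were lower, among them Lef1 and Lgr5 (at least 13.7-fold), and Ccnd1 was 17.0-fold higher, with a list median of -2.46. Of 10 Hedgehog genes 5 were lower and none higher, including Gli1 (at least 23.7-fold) and Ptch1 (9.06-fold), with a median of -2.24, or -1.88 with bounds.

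**Figure D2:**
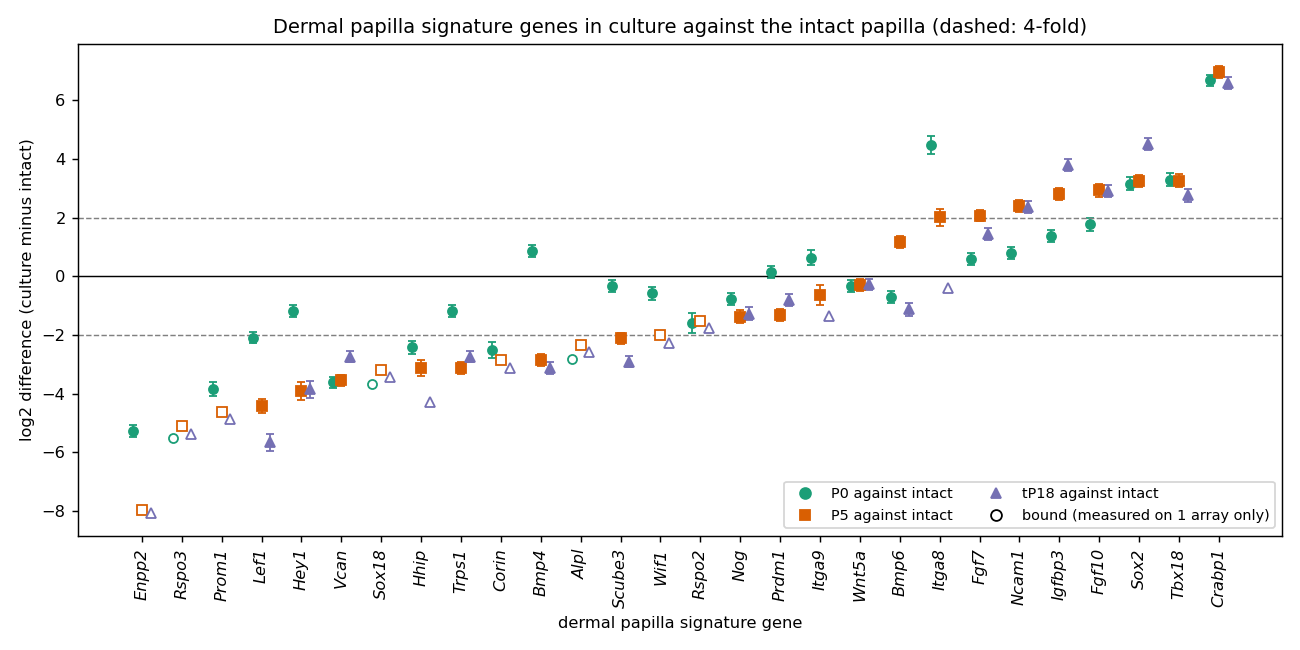
Log2 difference from the intact papilla of each measured dermal papilla signature gene in P0, P5 and tP18, ordered by P5, with the scanner's spot error as bars, open symbols for bounds and dashed lines at 4-fold. Crabp1 lay between 6.60 and 6.96 in the 3 cultures, and Enpp2 was at -5.27 in P0.

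The lists of arrest, secretion, matrix and contraction were high in P5. Of 16 p53 targets and CDK inhibitors 9 were at least 4-fold higher and none lower (median 2.70), including Ccng1 at 39.4-fold. Of 15 senescence-associated secretory genes 9 were higher and 1 was lower (median 3.51, and 2.81 with bounds), with Mmp3 500-fold higher, Mmp10 at least 240-fold higher and Igfbp5 at least 85.6-fold lower. Of 13 contractile genes 12 were higher (median 4.36), led by Ccn1 (116-fold), Actg2 (57.3-fold) and Acta2. Of 24 extracellular matrix genes 13 were higher, such as Tnc (292-fold), Lox (94.1-fold) and Bgn (23.9-fold), and 4 were lower, among them Dcn (202-fold), Eln (at least 26.1-fold) and Col3a1 (17.7-fold). In the list of secreted growth factors, 7 of 20 were higher and 3 lower, with Edn1 at least 57.0-fold and Inhba 17.8-fold higher, and Fgf5 25.2-fold lower. Cell cycle genes all lay within 4-fold, with a median of -0.08 that became 0.55 with scaling to the median. Among the highest genes overall were Adm (553-fold), Mmp3, Thbs1 (329-fold) and Sema3a (302-fold), and the lowest were Hba-a1 (750-fold), Krtap8-1 (409-fold), Sostdc1 (350-fold), Dcn and Krt28 (195-fold). Among genes measured on 1 array only, Grem1, Akr1c18 and Spp1 were at least 1290-fold, 385-fold and 327-fold higher, and Hba-a2, Krt5 and Prr9 at least 1700-fold, 1310-fold and 649-fold lower. Under 4-fold in other settings were Bmp4 with the mean of its probes (log2 -1.79), Alpl with scaling to the median (-1.70) and quantiles (-1.74), and Alpl, Corin, Lgr5 and Ptch1 with normexp.

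The transfected cells differed from the intact papilla at least 4-fold in 14 lower and 6 higher genes of the signature, and 6 of 13 contractile genes were higher. Sox2, a transcription factor of papilla subsets and of stem cells, was 22.8-fold higher in tP18 than in the intact papilla (log2 4.51 ± 0.21). Lef1 was 50.5-fold lower (log2 -5.66 ± 0.29), Bmp4 8.67-fold lower (log2 -3.12 ± 0.21) and Vcan 6.69-fold lower (log2 -2.74 ± 0.20). Cdkn2a was 42.4-fold higher (log2 5.41 ± 0.31) and Cdkn1a 6.26-fold higher (log2 2.65 ± 0.21). Among 16303 genes compared, 1000 were at least 4-fold higher and 1067 at least 4-fold lower. Higher genes made up 48.4% of these, against 33.5% when scaled on probes detected on all arrays, 31.5% in the authors' value table and 68.1% with scaling to the median.

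The signature had 14 of 28 members at least 4-fold lower in tP18 and 6 higher, with a median of -2.83 (percentile 0), -2.02 with bounds and -0.80 over members measured on both arrays. Enpp2 was at least 271-fold, Rspo3 at least 41.3-fold, Corin at least 8.68-fold and Alpl at least 6.04-fold lower, whereas Crabp1 was 96.8-fold and Igfbp3 14.0-fold higher. The keratinocyte and hair shaft list again had 21 of 24 members lower (median log2 -6.79), the melanocyte list 8 of 10 (-5.66) and the endothelial list 10 of 12 (-2.99), and with bounds these medians were -6.06, -4.51 and -2.44. Of 14 immune genes, 4 were lower and none higher (median -1.30, percentile 0.01). In the BMP list 5 of 16 members were at least 4-fold lower and 2 higher (median -1.19, percentile 0). Sostdc1 was at least 514-fold, Msx2 72.2-fold and Bmp7 at least 22.6-fold lower, and Grem1 was at least 1060-fold and Fst 18.2-fold higher. Of 13 Wnt targets 8 were lower (median -3.10), among them Apcdd1 and Lgr5, both at least 16.4-fold. Hedgehog genes had 5 of 10 lower (median -1.66), including Gli1 at least 28.3-fold and Hhip at least 19.4-fold, and their median was -0.23 at percentile 8.68 over members measured on both arrays. The 16 p53 targets and CDK inhibitors had 8 higher and none lower (median 1.92), with Pmaip1 at 18.4-fold. Of 15 senescence-associated secretory genes 8 were higher and 2 lower (median 3.21, or 2.76 with bounds), led by Timp1 (39.0-fold) and Mmp3 (32.4-fold), with Igfbp5 at least 102-fold and Ccl8 at least 6.25-fold lower.

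Contractile genes had 6 of 13 members higher in tP18, such as Ccn1 (36.5-fold) and Cnn2 (14.7-fold), and Myl9, the regulatory light chain of smooth muscle myosin, was 9.19-fold lower. Their median of 1.86 was 0.42, at percentile 27.1, when all probes of a gene were averaged. Of 23 extracellular matrix genes 9 were higher, including Tnc (45.8-fold) and Fn1 (9.18-fold), and 7 were lower, including Dcn (at least 526-fold) and Col3a1 (48.3-fold). The highest genes overall in tP18 were Gap43 (265-fold), Adm (212-fold), Sema3a (200-fold), S100a4 (131-fold) and Il1rl1 (125-fold). The lowest were Perp (1420-fold), Krt5 (1170-fold), Mycn (750-fold), Hba-a1 (527-fold) and S100a14 (491-fold). Measured in tP18 but not well above background in the intact papilla, Nefl, a neurofilament subunit, was at least 315-fold higher. In the opposite direction, Hba-a2, Prr9 and Gjb2 were at least 2030-fold, 776-fold and 661-fold lower. With normexp, Alpl, Apcdd1, Ccl8, Corin and Lgr5 were under 4-fold.

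P5 and P0 compared the later with the earlier passage of untransfected cells. In P5, 5 of 13 contractile and 5 of 16 senescence-associated secretory genes were at least 4-fold higher, whereas Bmp4, Igf1 and the Wnt antagonist Sfrp2 were lower. Acta2 was 9.35-fold higher in P5 than in P0 (log2 3.23 ± 0.20) and Cdkn2a 4.60-fold higher (log2 2.20 ± 0.20), the latter under 4-fold with scaling on detected probes (1.87), quantiles (1.82), the authors' table (1.72) and the mean of its probes (1.65). Bmp4 was 13.2-fold lower (log2 -3.72 ± 0.21), the growth factor gene Igf1 13.5-fold lower (log2 -3.76 ± 0.21) and Lef1 5.02-fold lower (log2 -2.33 ± 0.23), the last under 4-fold with scaling to the median (-1.86), normexp (-1.28) and the mean of its probes (-1.62). Sox2 and Vcan differed by 0.08 ± 0.20 each on the log2 scale, with a sign that depended on the scaling. Other Vcan probes were not alike: 1 read 0.22 in P0 and 0.16 in P5 on the scaled log2 axis. A dimmer probe read -2.25 in P0 and was not well above background in P5 (-4.21). Of 15432 genes compared, 155 were at least 4-fold higher and 195 at least 4-fold lower, a share of 44.3% higher. The share was 20% with scaling on probes detected on all arrays, 12.1% in the authors' value table, 58.5% with normexp, 63.1% after quantile normalization and 83.9% with scaling to the median.

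In the signature, 5 of 25 members were lower in P5 than in P0 and none higher (median -0.98, percentile 0, or -0.60 with bounds), led by Bmp4, Hey1 (6.57-fold) and Enpp2 (at least 6.45-fold). Of the markers of other cells, no keratinocyte or endothelial gene was 4-fold apart, while 1 of 6 melanocyte genes (Mitf, 4.14-fold) and 2 of 14 immune genes (Tyrobp, 9.07-fold, and Fcer1g, at least 6.86-fold) were lower in P5, as was the pericyte gene Rgs5 (4.89-fold). The medians of the immune (-0.74, percentile 0.28), Schwann and nerve (-0.80, percentile 0.67) and melanocyte (-1.26, percentile 0.18) lists were low as well, the last at percentile 27.4 with bounds and 30.2 with normexp. Among 11 Wnt targets 4 were lower (median -1.72, or -1.43 with bounds), including Ccn5 at 14.7-fold. Of 13 contractile genes 5 were higher and none lower (median 1.71), including Ccn2 (7.20-fold) and Actg2 (6.52-fold). Of 16 senescence-associated secretory genes 5 were higher and none lower (median 1.61, or 1.42 with bounds), with the chemokines Ccl7 and Ccl2 at 5.75-fold and 5.13-fold. The 26 cell cycle genes all lay within 4-fold, and their median of 1.08 lay above all 10000 random lists. This shift was not particular to them, as housekeeping genes had a median of 0.987 (percentile 97.75). In lists chosen after the values were seen, ribosomal protein genes were at 0.975 and respiratory chain genes at 1.004, both at percentile 100. In the extracellular matrix list, Fbln2 (7.49-fold) and Tnc (7.48-fold) were higher and Loxl2 (6.42-fold, but log2 -0.68 with the mean of its probes) and Postn (at least 5.66-fold) lower. The highest genes overall were Lce3a (82.3-fold), Efemp1 (18.6-fold), Esm1 (18.3-fold), Klra4 (16.6-fold) and Crct1 (13.8-fold). The lowest were Sfrp2 (29.0-fold), Pcp4 (28.6-fold), Apod (15.9-fold), Epb41l4b (15.1-fold) and Ccn5. Also under 4-fold in other settings were Ccl2 with quantiles and in the authors' table (log2 1.88 in both), Mitf and Rgs5 with scaling to the median (-1.59 and -1.83) and quantiles (-1.76 and -1.91), Mitf with the mean of its probes (-1.39), and Enpp2, Epb41l4b, Fcer1g, Hey1, Mitf, Postn, Rgs5 and Tyrobp with normexp.

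The transfected cells were then set against P5, the later untransfected passage; transfection and passage number differ together in this comparison. At least 4-fold lower in tP18 were 6 of 13 contractile, 9 of 15 senescence-associated secretory and 7 of 24 extracellular matrix genes, while no cell cycle gene differed 4-fold. Acta2 was 146-fold lower in tP18 than in P5 (log2 -7.19 ± 0.21), Actg2 102-fold (log2 -6.68 ± 0.25) and Myl9 89.7-fold lower (log2 -6.49 ± 0.21). Cdkn2a was 3.26-fold lower (log2 -1.70 ± 0.20) and Cdkn1a 2.38-fold lower (log2 -1.25 ± 0.20), while Sox2 was 2.41-fold higher (log2 1.27 ± 0.20) and Vcan 1.75-fold higher (log2 0.81 ± 0.20). On the scaled log2 axis, the second Cdkn2a probe differed less, at -2.66 in P5 and -3.47 in tP18. The second Cdkn1a probe differed more, at 2.79 in P5 and 0.98 in tP18. Lef1 was 2.36-fold lower (log2 -1.24 ± 0.31), and Alpl and Corin were not well above background on either array. Of 14701 genes compared, 65 were at least 4-fold higher in tP18 and 433 at least 4-fold lower.

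Of 13 contractile genes, 6 were at least 4-fold lower in tP18 and none higher (median -1.67, percentile 0). Of 15 senescence-associated secretory genes 9 were lower (median -2.99, or -2.54 with bounds), including Ccl7 (40.5-fold) and Mmp10 (30.7-fold), while the EGF family ligand Areg was at least 13.2-fold higher. Of 24 extracellular matrix genes 7 were lower and none higher (median -1.42, or -1.28 with bounds), led by Fbln2 (at least 283-fold), Col6a3 (at least 23.8-fold) and Lox (21.1-fold). The p53 targets and CDK inhibitors had a median of -0.65 (percentile 0.05), with Cdkn2b 4.03-fold lower, but under 4-fold in 5 other settings (log2 between -1.76 and -1.97), and the other 14 measured members within 4-fold. All 26 cell cycle genes lay within 4-fold, with a median of 1.1 at percentile 100. The Polycomb and telomerase list had no member 4-fold apart and a median of 0.48 at percentile 99.98. In the dermal papilla signature, none of 20 members was 4-fold higher and 2 were lower, Itga8 (at least 5.33-fold) and Bmp6 (4.85-fold), and the median of -0.14 lay at percentile 32.0. The keratinocyte, melanocyte and endothelial lists had no member 4-fold apart. However, 3 of 7 dermal fibroblast and sheath genes were lower, namely Mfap5 (16.5-fold), Cd34 (9.12-fold) and Thy1 (5.85-fold), as was Laptm5 (11.4-fold) of 13 immune genes, and the pericyte median was -0.96 at percentile 0.62. The fibroblast and sheath median was 0.07 at percentile 72.4, so that list was not lower as a whole. Of 19 secreted growth factors 4 were lower and none higher (median -0.84, percentile 0.01), including Edn1 (31.1-fold), Igf2 (20.7-fold) and Igf1 (6.68-fold). The Wnt antagonists Dkk3 (20.5-fold) and Frzb (at least 14.6-fold) were lower, and the BMP list member Fst was 4.54-fold higher.

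Over all genes measured on both arrays, the highest in tP18 against P5 were Pthlh (16.6-fold), Tinag (11.9-fold), Ngef (11.1-fold), Dlx1 (9.55-fold) and Nefl (9.07-fold). Cyba, a subunit of the NADPH oxidase, was 136-fold lower, second to Acta2. Among genes measured on 1 array only, Pax9 and Rgcc were at least 34.1-fold and 12.2-fold higher, and Sparcl1 and Kif1a at least 503-fold and 224-fold lower. Under 4-fold in other settings were Igf1 with the mean of its probes (log2 -1.29) and Areg, Bmp6, Cd34, Dlx1, Frzb, Igf1, Itga8, Rgcc and Tinag with normexp.

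Against P0, the transfected cells differed in part of the cell cycle, matrix and papilla lists. Of 26 cell cycle genes 13 were at least 4-fold higher and none lower (median 2.01, percentile 100), a count that depends on the scaling because the median lay between 1.63 and 2.34 over the scalings. They were led by the replication licensing genes Mcm3 (5.90-fold), Mcm2 (5.44-fold) and Mcm5 (5.34-fold). Other lists shared part of this shift, as housekeeping genes had a median of 0.709 (percentile 93.5). In lists chosen after the values were seen, ribosomal protein genes were at 0.827 (percentile 100) and respiratory chain genes at 0.64 (percentile 99.3). In the signature 6 of 25 were lower (median -1.55, percentile 0, or -0.60 with bounds), including Itga8 (at least 29.3-fold), Bmp4 (15.8-fold) and Lef1 (11.8-fold), and Igfbp3 was 5.35-fold higher. Of 24 extracellular matrix genes 9 were lower (median -1.77, or -1.61 with bounds), such as Col12a1 (at least 62.5-fold) and Col6a3 (at least 49.3-fold). The dermal fibroblast and sheath list had a median of -1.39 (percentile 0.01), or -0.93 with bounds, with Thy1 6.15-fold and Cd34 4.89-fold lower. Also lower were 2 of 14 immune genes (median -0.73, percentile 0.21, but -0.20 at percentile 3.25 with normexp), Laptm5 (22-fold) and Tyrobp (at least 15.7-fold), and 1 of 5 pericyte genes (median -1.13, percentile 0.51), Rgs5 (at least 9.79-fold). Bmi1 was 2.0-fold higher (log2 1.0 ± 0.2) and Sox2 2.55-fold higher (log2 1.35 ± 0.20). The second Bmi1 probe differed less, at -1.35 in P0 and -0.65 in tP18 on the scaled log2 axis. Of 15510 genes, 272 were at least 4-fold higher and 511 lower, a share of 34.7% higher that was 21.3% with scaling on probes detected on all arrays, 15.8% in the authors' value table and 56.4% with scaling to the median. The highest were Klra4 (43.1-fold), Pthlh (33.7-fold), C1ql3 (21.9-fold), Fst (20.7-fold) and Nefl (20-fold), and the lowest Cck (346-fold), S100g (268-fold), Ltbp2 (123-fold), Igf1 (90.3-fold) and Pcp4 (67.7-fold). Under 4-fold in other settings were Cd34 with scaling to the median (log2 -1.97), Lef1 with the mean of its probes (-1.85) and Cd34, Lef1, Mcm2, Rgs5 and Tyrobp with normexp.

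**Figure D3:**
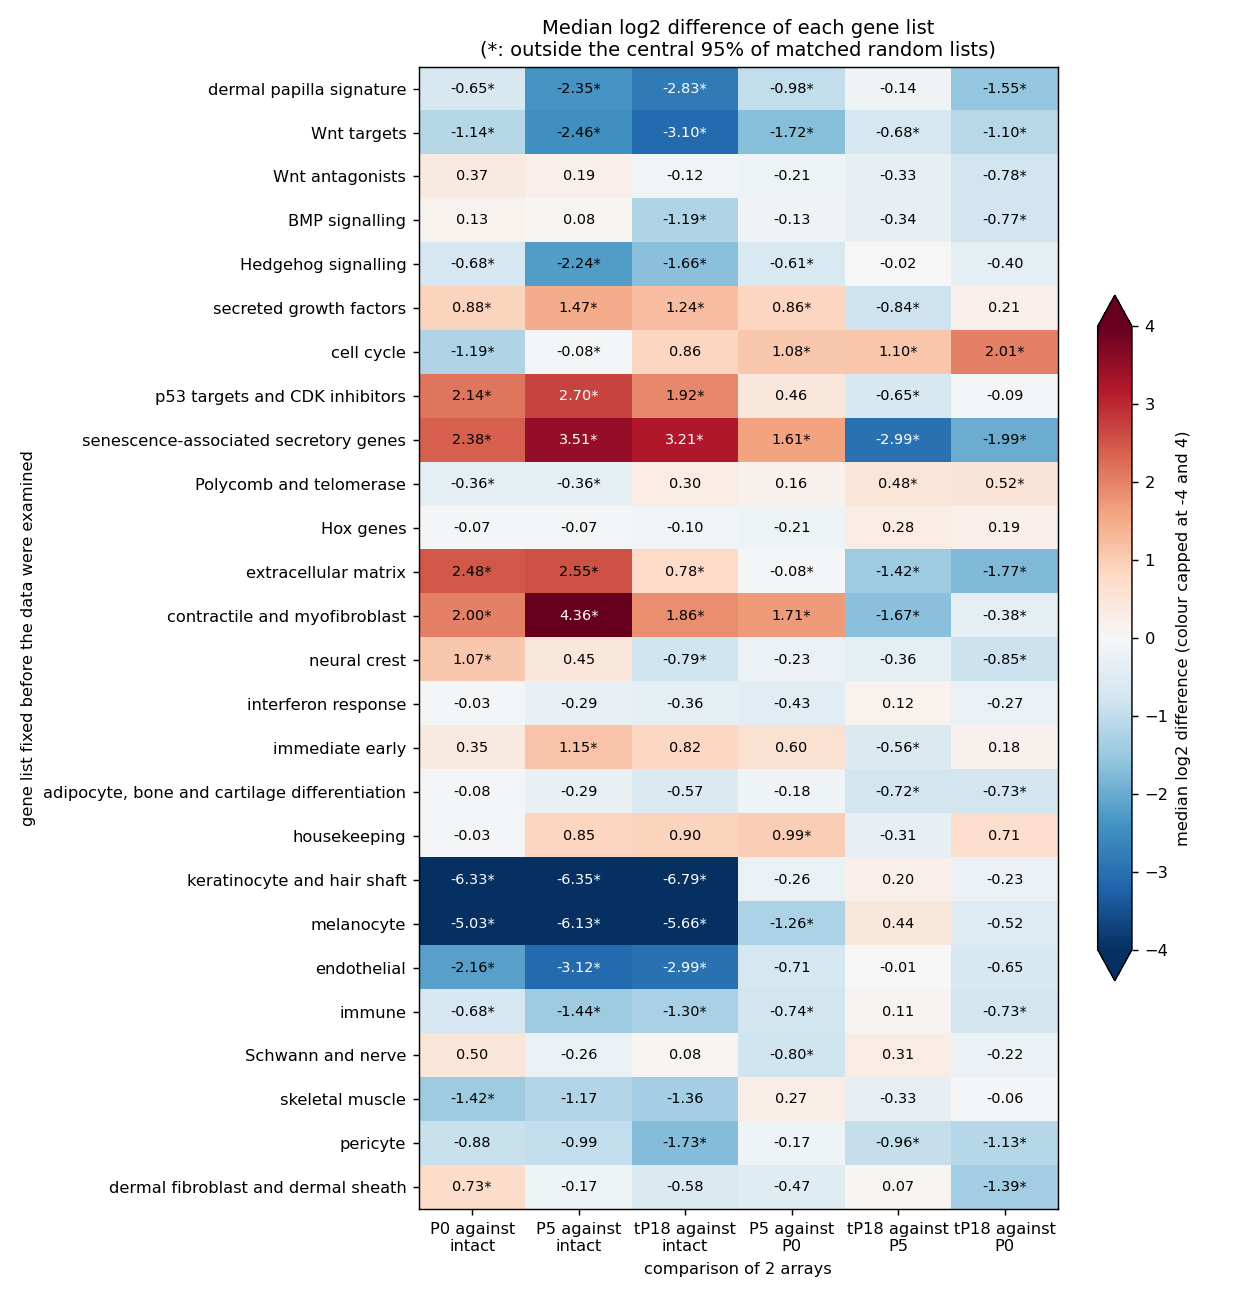
Median log2 difference of 26 gene lists in the 6 comparisons of 2 arrays, printed in each cell and coloured from blue (lower in the first-named array) to red (higher), with an asterisk where the median lay outside the central 95% of matched random lists. The contractile list read 4.36 in P5 against the intact papilla and -1.67 in tP18 against P5; for cell cycle and for Polycomb and telomerase in P5 against intact, and for extracellular matrix in P5 against P0, the sign turned with scaling to the median.

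The remaining lists were read against the intact papilla. Relative to the intact papilla, the Hox list had medians of -0.07, -0.07 and -0.10 in P0, P5 and tP18, whose sign depended on the scaling. Within it Hoxd8 was 11.4-fold, 26.3-fold and 45.8-fold higher in P0, P5 and tP18, the first under 4-fold with normexp (log2 1.46), and Hoxc13, a hair shaft regulator, was at least 83.6-fold, 59.6-fold and 71.3-fold lower. Medians of the interferon list (-0.03, -0.29 and -0.36) and of the adipocyte, bone and cartilage list (-0.08, -0.29 and -0.57) lay between percentiles 14.6 and 64.3, and those of P0 and P5 in both lists and of tP18 in the interferon list turned sign with some scalings. Immediate early genes had medians of 0.35, 1.15 and 0.82, with Dusp1 24.0-fold, 46.2-fold and 13.4-fold higher. Wnt antagonists had medians of 0.37, 0.19 and -0.12, the last 2 with a sign that depended on the scaling. Dkk2 was 35.8-fold, 49.7-fold and 69.3-fold higher. Neural crest genes had medians of 1.07, 0.45 and -0.79, of which the value in P5 was -0.05 in the authors' table. Housekeeping genes had medians of -0.03, 0.85 and 0.90, the first with a sign that depended on the scaling. The Polycomb and telomerase list had medians of -0.36, -0.36 and 0.30, of which the last 2 turned sign with some scalings. Among markers of other cells, the medians were 0.50, -0.26 and 0.08 for Schwann cells and nerve, -1.42, -1.17 and -1.36 for skeletal muscle, -0.88, -0.99 and -1.73 for pericytes, and 0.73, -0.17 and -0.58 for dermal fibroblasts and sheath. With bounds the pericyte medians were -0.40, -0.05 and -0.68 and the fibroblast median in P0 was 0.32. Of these marker medians, the Schwann and nerve values in P5 and tP18, the pericyte value in P5 and the fibroblast value in P5 turned sign with some scalings.

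Over 12835 genes well above background on all 4 arrays, the arrays of the cultures were closer to each other than to that of the intact papilla. Pearson's r across genes, which are not replicates, was 0.959 for P5 and tP18, 0.954 for P0 and P5, and 0.937 for P0 and tP18. With the intact papilla it was 0.887 for P0, 0.868 for tP18 and 0.842 for P5.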

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

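The tests on keratin-associated proteins, on signature members not shared with other cells, on olfactory receptor genes, on Sox2 over the scalings, on the number of Sox2 probes, on Y-linked genes in female donors and on Xist were chosen only after the result was seen. The rules of some tests were also changed after a first reading. For keratin-associated proteins, low medians would at first have counted for other cells in the papilla, and were later set to count for nothing where such a gene was already among the lowest genes. For the unshared signature members, a median below -1 in P5 and tP18 would at first have excluded the explanation, which the values met; a margin of the spot-to-spot spread was then added, and later each culture was read alone and the limit had to hold over 6 scalings and with bounds. For female donors, any Y-linked gene that stayed on would at first have excluded the explanation, and Sry was exempted after its values were read. For genomic DNA, the share of olfactory receptor genes well above background (22.7% in P0, the highest culture, against 26.8% in the intact papilla) was replaced by their share at or above Sox2, and then by the difference of each such gene from itself, since probes respond unequally.

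Some values pointed in opposite directions in different cultures, each against the intact papilla; with 1 array per group these differences were not tested. The neural crest list had a median log2 difference of 1.066 in P0 and -0.785 in tP18. Col6a3 was at 2.74 in P0 and -2.89 in tP18. Cyba was at 3.06 in P5 and -4.03 in tP18, Fbln2 at 3.86 and -4.29, and Myl9 at 3.29 and -3.20. Kif1a was at 4.18 in P0, 4.76 in P5 and -3.05 in tP18. In the opposite sense, Pax9 was at -2.32 in P0 and 3.26 in tP18, and Pthlh at -2.54 and 2.54. Values of genes not well above background on 1 of the arrays are bounds.

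Probes that name a genomic region and no gene, which entered no comparison above, also differed from the intact papilla. Of 16192 such probes, 278 were at least 4-fold higher and 288 lower in P0, 284 higher and 983 lower in P5, and 247 higher and 478 lower in tP18. The highest in each was the same probe, for the reverse strand of chromosome 12 from 82457625 to 82476325 in mm9, at 217-fold, 306-fold and 423-fold.

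Keratin, melanocyte and endothelial genes were far lower in all 3 cultures than in the intact papilla. Cells of other types in the dissected papilla are a candidate explanation. All 5 haemoglobin genes, a list chosen after the values were seen, were at least 4-fold lower in every culture, a sign of blood in that tissue. How far cells of other types account for the keratin, melanocyte and endothelial genes stays open. Keratin-associated proteins had medians no higher than -4.264 in any culture. However, they belong to the same hair shaft cells and Krtap8-1 (433-fold lower in P0) was already among the lowest genes, so they restate the pattern. Whether the papilla signature was lower only through members that epithelium, vessels or nerve share stays open in P5 and tP18. Its 16 other members had medians of 0.12 in P0 (percentile 81.0), -1.013 in P5 (percentile 0.68, 7 higher and 6 lower) and -2.01 in tP18 (percentile 0, 5 higher and 6 lower). In P0 they were not lower as a set, at 0.029 to 0.29 over the settings, in a division made after the values were seen. The medians in P5 and tP18 go against this explanation, but in P5 the median was -0.38 with scaling to the median, -0.51 with quantiles and -0.035 with normexp. In tP18 it was -0.495 with normexp, and that setting alone keeps the explanation open, as the median was -1.318 or lower in the others. Of the 29 signature genes 9 are also in another fixed list, and a true difference between papilla and culture remains untested.

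Sox2 was higher in culture while most of the signature that differed was lower. Genomic DNA in the amplified cDNA is argued against, because the median log2 difference of olfactory receptor genes from the intact papilla was at most 0.062 over 6 scalings and the 3 cultures, where a rise like that of Sox2 would have raised them too. The scaling is argued against too, since the lowest log2 difference of Sox2 over 6 scalings and the 3 cultures was 2.57. Cross-hybridization stays open, as only 1 probe reads Sox2. A difference that comes with culture itself may remain, as a hypothesis on 1 array per group.

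The Y-linked genes Ddx3y and Eif2s3y had intensities of 113 and 77.9 in the intact papilla and 86.1 and 51.5 in P0, and were not well above background in P5 or tP18, whereas Xist was at 2500, 2370, 1680 and 2990. Dimmer arrays are argued against: only 0.98% of 1633 genes of like level on the first 2 arrays were lost on both later ones. Cells from female donors in P5 and tP18 may explain the loss of these 2 genes, but Sry, read at 157, 195, 74.0 and 127, was well above background on all 4 arrays without following them, and Zfy1 was well above background only in tP18, at 24.9, not where those 2 were read, so both probes decide nothing. Loss of the Y chromosome or of male cells in culture cannot be told apart from this, and Xist (-0.06 in P5 against P0, log2) decides nothing, as either outcome would have been compatible with it. The Y-linked genes Kdm5d and Uty, dim in the intact papilla at 15.5 and 21.2, were not well above background in P0, P5 or tP18. They therefore do not place a loss between P0 and P5. If donors differed in sex, differences between the earlier and later arrays may hold donor effects.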

How the results depend on the processing

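No paired analysis was possible because each group is a single array, and leaving out an array was not possible for the same reason. The alternatives below were planned before the data were examined. Of 84 list medians outside the central 95% of random lists, all 84 stayed outside with the 3 scalings that shift whole arrays, which cannot change a percentile by construction. The number was 80 with quantile normalization, 76 with normexp, 75 with genes measured on both arrays only, 79 with the mean of a gene's probes and 75 with unmatched random lists. No named gene at least 4-fold apart turned its sign in any setting: of 447 such values, 431 stayed beyond 4-fold with scaling on probes detected on all arrays, 424 with scaling to the median, 424 with quantile normalization, 431 in the authors' table, 434 with the mean of probes and 325 with normexp. The normexp offset of 50 shrinks log2 differences of dim genes by construction. Median intensities were 44.7 in the intact papilla, 38.07 in P0, 20.35 in P5 and 26.7 in tP18. Normexp also starts from another signal, and the share of each cause was not tested. The median of all genes in P5 against the intact papilla was 0.30, and -0.12, 0.94, 0.28, 0.27 and -0.20 with scaling on detected probes, to the median, by quantiles, with normexp and in the authors' table. Signal over background limits P5 most, where 57.1% of probes were well above it.

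Counts of higher and lower genes follow, in the order P0, P5 and tP18 against intact, then P5 against P0, tP18 against P5 and tP18 against P0. At 2-fold, which admits more genes by construction, they were 2412 and 2208, 3986 and 3003, 3151 and 2840, 2176 and 1383, 784 and 1406, and 1835 and 1534. At 8-fold, which admits fewer, they were 347 and 390, 618 and 435, 406 and 577, 35 and 28, 12 and 158, and 50 and 215. With normexp they were 443 and 318, 791 and 328, 545 and 400, 55 and 39, 9 and 150, and 88 and 161. Counts that moved by over 1.5 times in other settings were the following. With genes measured on both arrays only, lower genes numbered 422, 499, 480, 118, 279 and 288, by construction, and 36 were higher in tP18 against P5. With scaling to the median, 2765 were higher and 550 lower in P5 against intact, 1662 higher in tP18 against intact, 434 higher and 83 lower in P5 against P0, and 488 higher in tP18 against P0. With scaling on detected probes, 1614 were lower in P5 against intact, 89 higher and 357 lower in P5 against P0, and 176 higher in tP18 against P0. In the authors' table, 947 were higher and 1782 lower in P5 against intact, 69 higher and 502 lower in P5 against P0, and 137 higher in tP18 against P0. With quantile normalization, 128 were lower in P5 against P0 and 42 higher in tP18 against P5. Scaling on detected probes, scaling to the median and the authors' table differ from the scaling used by 1 constant per array, which moves counts of higher and lower genes in opposite ways.

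The median of the dermal papilla signature stayed below 0 in every setting. In P0 against intact it was -0.479 with scaling to the median, -0.348 with normexp and -0.342 with genes measured on both arrays. In P5 against intact it was -2.774 with scaling on detected probes, -1.716 to the median, -0.682 with normexp, -2.852 in the authors' table, -0.466 on both arrays and -1.952 with the mean of probes. In tP18 against intact it was -3.178, -2.335, -0.755, -3.227 and -0.797 in the first 5 of these, and -3.128 with quantiles. In P5 against P0 it was -1.312, -0.515, -0.070, -1.462 and -0.310, and -0.503 with quantiles. In tP18 against P0 it was -1.806, -1.224, -0.222, -1.925 and -0.408, then -1.206 with quantiles and -0.935 with the mean of probes. In tP18 against P5 it was -0.284 to the median and -0.007 on both arrays. Of the medians outside the central 95% of random lists, 4 turned sign: with scaling to the median, cell cycle (0.554) and Polycomb and telomerase (0.269) in P5 against intact and extracellular matrix (0.384) in P5 against P0, where the array shift is the cause, and Wnt antagonists in tP18 against P0 on both arrays (0.062), where fewer genes enter. Many medians inside that range also turned sign between scalings. Beyond these constructions, the cause was not tested.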

Other observations

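The lists in this part were chosen after the values had been seen. Of 15 genes of glycolysis, 4 were at least 4-fold higher in P0 than in the intact papilla (median log2 1.03), 9 in P5 (2.03) and 8 in tP18 (2.04), while Aldoc was 5.04-fold lower in P5 and 5.56-fold lower in tP18. Hk1, the hexokinase of the first step, was 8.02-fold, 17.3-fold and 12.5-fold higher, and the glucose transporter gene Slc2a1 was 5.21-fold, 9.49-fold and 8.12-fold higher. Of 18 lysosomal genes, 7 were at least 4-fold higher in P0 (median 1.85), 12 in P5 (2.28) and 6 in tP18 (1.57), and none lower. The protease gene Ctsl was 17.2-fold, 19.1-fold and 14.8-fold higher, and Npc2, which moves cholesterol out of the lysosome, was 11.1-fold, 15.8-fold and 10.2-fold higher. Chaperone genes had medians of 0.60, 1.30 and 1.21, cholesterol synthesis genes 0.35, 0.93 and 0.96, ribosomal protein genes -0.33, 0.62 and 0.49, and respiratory chain genes -0.17, 0.85 and 0.50. The median of all genes was -0.04, 0.30 and 0.20. The ribosomal and respiratory values in P0 lay at percentiles 0 and 1.03, and those in P5 and tP18 between 30.2 and 88.3.

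Single genes better known from neurons were high in culture. Gap43, a growth cone protein, was 37.4-fold, 225-fold and 265-fold higher in P0, P5 and tP18 than in the intact papilla, and Nefl at least 15.7-fold, 34.7-fold and 315-fold higher. The wider list of neuronal cytoskeleton genes had medians of -0.12, 0.28 and -0.37, whose signs depended on the scaling. A list of craniofacial homeobox and forkhead genes had medians of -0.60, -1.45 and 0.19, the last 2 with a sign that depended on the processing, with 3 members lower in each culture and 1, 1 and 2 higher. Its members Pax9 and Dlx1 were higher in tP18 than in P5, Pax9 at least 34.1-fold and Dlx1 9.55-fold, but against the intact papilla Pax9, not well above background in P0 or P5, was at least 4.99-fold and 3.56-fold lower there, and Dlx1 was 5.16-fold lower in P5. In tP18 against P5 the list had 2 of 10 measured members at least 4-fold higher and none lower, with a median of -0.39 at percentile 6.24. In the same list, Lhx6 lay between 7.48 and 8.24 on all 4 arrays on the scaled log2 axis, and Dlx3, which hair matrix cells express, was 51.2-fold, 49.5-fold and 61.5-fold lower than in the intact papilla. Haemoglobin genes, a sign of blood in the dissected tissue, had all 5 members at least 4-fold lower in every culture, with medians of -9.84, -9.55 and -9.63.

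The share of region probes well above background was 67.1% in the intact papilla, 65.4% in P0, 49.9% in P5 and 57.4% in tP18. For probes of mRNA the shares were 74.7%, 72.1%, 65.6% and 66.9%. Olfactory receptor genes were well above background in 26.8%, 22.7%, 13.2% and 18.8% of 1072.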
